A study of Mus musculus with 6 samples.

How the data were processed

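Ribosome profiling sequences the short stretches of RNA that ribosomes shield from nuclease. Per the labels' protocols, round spermatids were lysed in the presence of cycloheximide and digested with RNase I, ribosomes were pelleted through a sucrose cushion, and the protected fragments were selected on a gel and made into libraries with a small RNA kit. The 6 samples fall into 3 wild-type and 3 Eif5a SKO samples by their genotype labels, and the replicate numbers come from the sample titles. The meaning of SKO is not spelled out in the labels. The table's own columns call the genotype cKO, and they were matched to the SKO samples by that name, the replicate number and the wild-type columns that remain.

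The deposited values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, computed by the authors and given as 1 value per gene symbol and library, with no counts. Cutadapt, Bowtie2, STAR and Cufflinks and the build mm10 are named per the submitters' processing notes, with no role or order; whether ribosomal RNA was removed, the annotation, and the treatment of multi-mapping reads are not given in the sources used here. FPKM are relative values, so a change in a few very abundant rows moves every other row of that library. The 3 densest rows of each library held between 24.6% and 46.4% of its summed FPKM. In all, 181 rows have the same 6 values as another row, 73 of them among the tested rows. Such rows are not told apart by the table, and the reason for the equal values was not examined.

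Absolute depth is unknown. Relative depth was taken from genes under 1 FPKM in every library, whose values step by what 1 read is worth. Of 2895 such genes 26.2% had values in whole-number steps within 2% after correction for relative depth, against 0.45% after shuffling values over genes. This share was too low to recover read counts for all genes, so no count model was used.

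Symbols were matched to a RefSeq gene table of GRCm38, the assembly behind mm10, by symbol for 19305 rows and by synonym for 81 rows, and 3384 rows were unmatched. Coordinates come from that table. Rows with a mean of at least 1 FPKM over the 6 libraries were tested, 15578 rows, and 7192 rows were left out. A pseudocount of 1 was added, log2 was taken, and SKO was compared with wild type with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over all tested rows and a threshold of 0.05. The values were used as deposited with no further scaling. Fold changes on the log2(FPKM + 1) scale understate the change of genes with low values. p-values measure the spread between these samples. For Eif5a an exact permutation test was added.

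In all, 25 gene lists were fixed before the data were examined and 24 were tested. The list of mitochondrially encoded genes had no members in the table. Lists with at least 4 tested members were compared with all other genes by camera with a preset correlation of 0.01, with adjustment over the 24 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation 0 lists passed. Fry, which asks whether a list's genes move one way on balance, called 2 with the deposited values, the Leydig and Sertoli cell lists. Under the TMM-type scaling described below it called 4. They were the post-meiotic sex-linked, testis histone variant, Sertoli cell, and integrated stress and unfolded protein response lists. Members past the test were counted over all genes and adjusted over the list alone.

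Genes named in the text follow a rule fixed before the data were examined. It takes Eif5a, and the 8 genes with the largest and the 8 with the smallest log2 fold change among those past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between groups. It also takes, in each list, the 2 members past the threshold with the smallest p, or the 2 with the highest mean where none passed. Rows named by a Gm number, a Rik clone, a LOC number or an identifier alone and ribosomal protein pseudogenes were counted but not named. The rule gave 8 genes that rose and 1 that fell from the ranking and 49 genes in all. Groups of 3 against 3 fail to overlap in 10% of genes by chance. Further members of the lists, genes past the test under TMM-type scaling and X-linked examples were named after their values were seen.

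Results were recomputed with pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, TMM-type scaling (a trimmed mean of log ratios to a reference library, trimming 0.3 of the ratios and 0.05 of the levels at each end), quantile normalization, rescaling to equal sums (TPM), eBayes without a trend or with robust estimation, the replicate number as a block, and leaving out each library in turn. The TMM-type factors ran from 0.812 to 1.31. A planned test of proline runs needed coding sequences and was not run.

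The fit was tested on simulated data with the same group sizes over 14860 genes. With unscaled values it recovered 6%, 72%, 92% and 100% of 50 genes changed by 1, 2, 3 and 4 on the log2 scale, and called 12 of 14610 unchanged genes. With TMM-type scaling it recovered 18%, 78%, 92% and 100% and called 9. The changed genes were drawn from those with a mean scaled log2(FPKM + 1) of at least 3, so recovery at lower values was not tested. In the same simulation a shifted list was found and 0 of 23 unshifted lists were called. The simulated noise was independent between genes, so it could not show false list calls that come from correlated genes. Bootstrap intervals of medians used 2000 resamples of genes. Figures were drawn with matplotlib 3.10.9.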

Results

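Ribosome-protected fragments were sequenced from round spermatids, the haploid cells that form after meiosis and later elongate into sperm. The cells were taken from mouse testis, in 3 wild-type samples and 3 samples of a genotype labelled Eif5a SKO. EIF5A is the translation factor that carries the amino acid hypusine and helps ribosomes move through difficult stretches of coding sequence. The series title names translational control and the reorganization of the chromocenter, the cluster of centromeric heterochromatin in the spermatid nucleus. The comparison of the 2 genotypes therefore asks which genes carried more or fewer ribosome footprints when Eif5a was targeted. The series design text, which is written for an accessibility assay, gives 3 sorted mice per group. Each of the 6 libraries is given as footprint density in FPKM for 22770 gene rows, and 15578 rows with a mean of at least 1 FPKM were tested. Footprint density reflects the amount of mRNA, how often it is translated and how fast ribosomes move along it. Matched RNA levels are not analysed here, so a rise or fall is not by itself a change in translation.

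The absolute depth of the libraries is unknown. The steps between low values gave relative depths, with SKO replicate 1 set to 1. The wild-type replicates 1, 2 and 3 lay at 0.787, 0.760 and 0.631, and SKO replicates 2 and 3 at 0.503 and 0.771. A median low gene gained between 0.122 and 0.243 FPKM per read in the different libraries, so values near 1 FPKM rest on few reads. Protein-coding rows held 26.1%, 22.5% and 28.5% of the summed FPKM in the wild-type libraries and 18.3%, 33.1% and 29.8% in the SKO libraries. The remainder lay mostly in small RNAs and in rows that are not in the reference table. Spearman correlations over protein-coding rows, which are not independent replicates, ran from 0.847 to 0.871 between libraries of one group and from 0.824 to 0.848 between groups.

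Eif5a footprints were strongly reduced in the SKO samples. The gene (identifier 276770, GRCm38 chromosome 11, 69916712 to 69921958) had 34.2, 48.8 and 61.9 FPKM in the wild-type replicates and 1.84, 1.93 and 2.99 FPKM in the SKO replicates. The group means were 48.3 ± 13.9 FPKM (SD, n = 3) and 2.25 ± 0.642 FPKM (SD, n = 3), so the SKO mean was 4.67% of the wild-type mean, a 21.4-fold difference. On the log2(FPKM + 1) scale the change was -3.90 (SE 0.37, limma, adjusted p = 0.00641). The groups did not overlap, and the two-sided exact permutation test gave p = 0.1, the smallest value that 20 assignments of 3 against 3 allow. The pseudogene Eif5al3-ps, whose reads can be shared with Eif5a, had 18.1 ± 5.09 FPKM in wild type and 2.90 ± 1.21 FPKM in SKO (SD, n = 3; limma adjusted p = 0.0756). It fell under TMM-type scaling (scaled log2 fold change -2.44, limma adjusted p = 0.0216).

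Among protein-coding genes, footprints rose in the SKO samples on Cacnb4, Tfrc, Sly, Dcn and a group of X-linked histone H2A variant genes, and fell on Eif5a. Cacnb4, which encodes a beta subunit of voltage-gated calcium channels, went from 0.294 ± 0.0924 to 8.61 ± 2.46 FPKM (SD, n = 3 per group). Its log2 fold change was 2.86 (SE 0.34, adjusted p = 0.0244). Tfrc, the transferrin receptor that takes iron into cells, went from 2.69 ± 0.189 to 18.9 ± 5.37 FPKM (log2 fold change 2.40, adjusted p = 0.0470). H2al1c, H2al1d, H2al1f and H2al1i encode histone variants of spermatids. They share the same 6 values, so the table does not tell them apart, and they went together from 1.16 ± 0.237 to 13.1 ± 3.39 FPKM (log2 fold change 2.69, adjusted p = 0.0244). Sly, a multicopy Y-linked gene known to act on the sex chromosomes of spermatids, went from 2.79 ± 1.01 to 22.5 ± 7.27 FPKM (log2 fold change 2.62, adjusted p = 0.0474). Copies of Sly can share reads as well. Eif5a passed in all 20 alternative settings, while the call was lost in part of them for the others: Cacnb4 passed in 10 of 18, H2al1c in 12 of 20, Sly in 8 of 20, Tfrc in 7 of 20 (largest adjusted p = 0.20, limma) and Dcn in 6 of 20.

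In all, 17 rows were higher and 3 lower in SKO at an adjusted p under 0.05 (limma, Benjamini-Hochberg, two-sided), and 1710 rows had an unadjusted p under 0.05. Of the 17 higher rows, 8 were protein coding, 5 were non-coding RNA genes, 1 was a pseudogene and 3 are not in the reference table. The top-ranked row was the microRNA gene Mir190b, listed at 0 in the 3 wild-type libraries and at 125, 248 and 162 FPKM in the SKO libraries. After multiplication by relative depth those 3 values were equal (1, 1 and 1), the pattern of the same small read number in each library. Whole-number ratios of this kind, within 2% and up to 12 reads, occurred in 5 of the 20 called rows, 4 of them at 0 in every wild-type library, and in 4.97% of all tested rows. Across all tested genes the median log2 fold change was 0.13 with the deposited values. The median was 0.003 after each library was divided by a TMM-type scaling factor, and changes of gene groups are given relative to the all-gene median. Under TMM-type scaling 159 rows passed, 119 higher and 40 lower, a share of 74.8% higher against 85% with the deposited values, and they include all 20 rows called without it. Counting rows with identical values once left 7 higher and 2 lower rows, and leaving out 1 library gave 4 to 31 rows with the deposited values and 4 to 28 under TMM-type scaling.

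**Figure D1:**
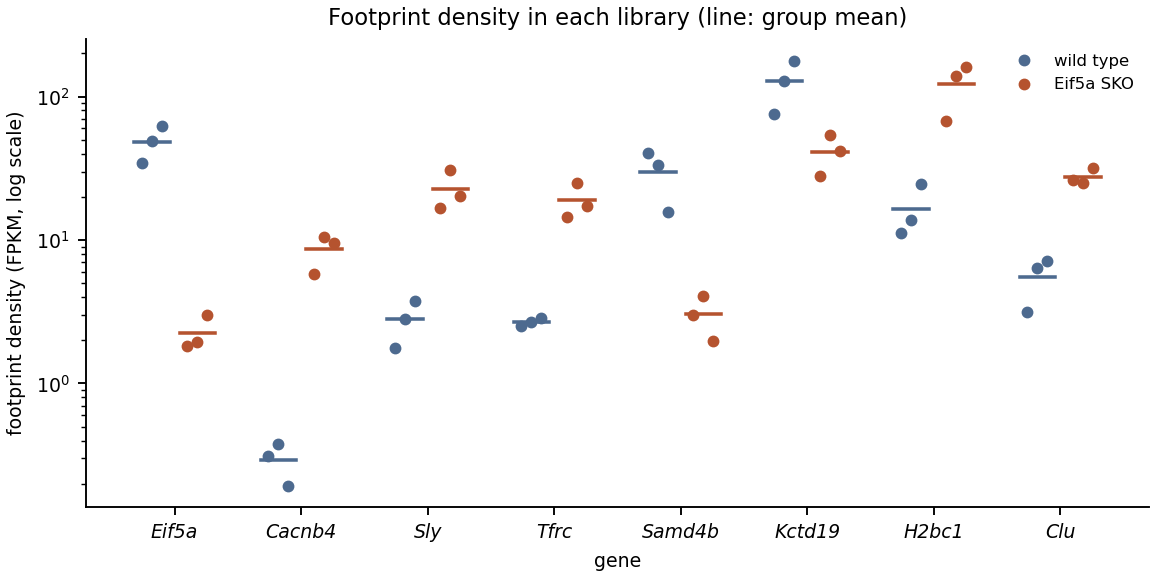
Footprint density in FPKM on a log axis for 8 genes in the 3 wild-type and the 3 Eif5a SKO libraries, with points for libraries and lines for group means (Eif5a means 48.3 and 2.25 FPKM). The groups do not overlap for any of the 8 genes, each of which passed the test with the deposited values or with TMM-type scaling.

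TMM-type scaling brought further genes past the test. They are named here after their values were seen. Among protein-coding genes with a mean of at least 5 FPKM in the higher group, and leaving out clone names, the largest further decreases were on Samd4b, Baz2b, Cabcoco1, Tuba3a, Tuba3b and Efcab5. Samd4b encodes a homologue of the RNA-binding translational repressor Smaug, and went from 29.9 ± 12.9 to 3.03 ± 1.06 FPKM (SD, n = 3 per group; scaled log2 fold change -3.02, limma adjusted p = 0.0410). Baz2b, a bromodomain chromatin protein gene, went from 30.9 ± 3.58 to 6.72 ± 1.14 FPKM (scaled log2 fold change -2.21). The testis alpha-tubulin gene Tuba3a went from 1777 ± 659 to 511 ± 183 FPKM and its paralogue Tuba3b from 1422 ± 539 to 414 ± 155 FPKM, and reads can be shared between them. Cabcoco1 went from 126 ± 46.1 to 29.9 ± 10.1 FPKM and Efcab5 from 109 ± 51.9 to 28.8 ± 5.88 FPKM. By the same limits the largest further increases were on H2bc1, the testis-specific histone H2B gene, and on Tmsb15b1 and Tmsb15b2, which encode thymosin-type actin-binding proteins. H2bc1 went from 16.5 ± 7.20 to 122 ± 48.6 FPKM (scaled log2 fold change 2.64, limma adjusted p = 0.0186). With the deposited values these 9 genes had adjusted p between 0.0579 and 0.263.

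Genes of the sex chromosomes that are active after meiosis shifted upwards as a group. The fixed list of post-meiotic sex-linked genes had 30 tested members with a median log2 fold change 0.42 above that of all genes, and 28 of the 30 lay above the all-gene median. The list passed the test (camera, adjusted p = 5.87e-07), but not with an estimated correlation between genes (adjusted p = 0.780 with an estimated correlation). One member, Sly, rose in the test over all genes, and 10 rose when adjusted over the list alone, with 20 not past the test. Under TMM-type scaling 6 members rose over all genes (Sly, Cypt1, Cypt2, Cypt3, Fthl17a and Slxl1) and 9 when adjusted over the list alone. Among the 10 were Cypt1 and Cypt2, which encode basic spermatid proteins, at 8.97 ± 3.23 against 43.2 ± 12.7 FPKM and 11.4 ± 2.61 against 51.3 ± 12.9 FPKM (wild type against SKO, SD, n = 3). Slxl1, an X-linked relative of Sly, had 88.1 ± 21.1 FPKM in wild type and 243 ± 86.8 FPKM in SKO. Cypt3, a further member of the Cypt family, had 7.74 ± 3.29 and 30.5 ± 4.61 FPKM. The Y-linked housekeeping-type genes Uba1y, at 3.85 ± 1.31 and 3.53 ± 0.457 FPKM, and Eif2s3y, at 39.8 ± 20.1 and 43.6 ± 14.3 FPKM, did not pass the test.

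The shift extended over the X chromosome, a comparison chosen after the values were seen. The 364 tested protein-coding genes of the X had a median scaled log2 fold change of 0.65 (95% bootstrap interval over genes 0.56 to 0.75), and 87.6% of them lay above the all-gene median. The medians of the 19 autosomes lay between -0.08 and 0.08. The 24 tested Y-linked genes had a median of 0.91 (0.25 to 1.44). With the deposited values the X median was 0.65 above the median of all genes, against 0.42 for the fixed list of post-meiotic sex-linked genes. The rise was thus not particular to that list. In each library, the median log2 level of X-linked genes minus that of autosomal genes was -0.30, -0.29 and -0.25 in wild type and 0.39, 0.54 and 0.27 in SKO. These 6 values gave a two-sided exact permutation p of 0.1, the smallest possible. Under TMM-type scaling 50 X-linked genes rose and 0 fell (limma, adjusted p under 0.05), against 34 of 10795 other protein-coding genes that rose. With the deposited values 4 X-linked genes rose. These are H2al1c, H2al1d, H2al1f and H2al1i, which share the same 6 values and so are not separate measurements. The 50 are not 50 separate measurements: they hold 45 distinct sets of 6 values and 21 have a Gm or Rik name. Only 3 of the 50, namely Slxl1 and Rik clones, have no relative with the same name root. The root is the leading letters of a symbol. All Gm names therefore share a root, and Rik names that begin with a digit match no other. The count thus says little about which of the 50 share reads. The X-linked calls of single genes were lost with fewer samples: 9 X-linked genes passed without wild-type replicate 1 and 0 when any of the other 5 libraries was left out. The X-linked minus autosomal median kept its direction, at 0.683 with TMM-type scaling and 0.645 to 0.753 with 1 library left out, but moved to 0.362 with a pseudocount of 5 and 0.392 with no filter on low values, both without TMM-type scaling. Under TMM-type scaling, camera on the X-linked genes as a set gave an unadjusted p of 2.34e-27 with the preset correlation of 0.01. With an estimated correlation of 0.0501 camera gave an unadjusted p of 0.00592. For the fixed sex-linked list the same camera test gave an unadjusted p of 0.00913, or 0.219 adjusted over the 24 lists. An example among genes used by many cell types is Cul4b, a ubiquitin ligase scaffold gene with 25.3 ± 6.17 FPKM in wild type and 69.0 ± 20.2 FPKM in SKO (SD, n = 3).

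**Figure D2:**
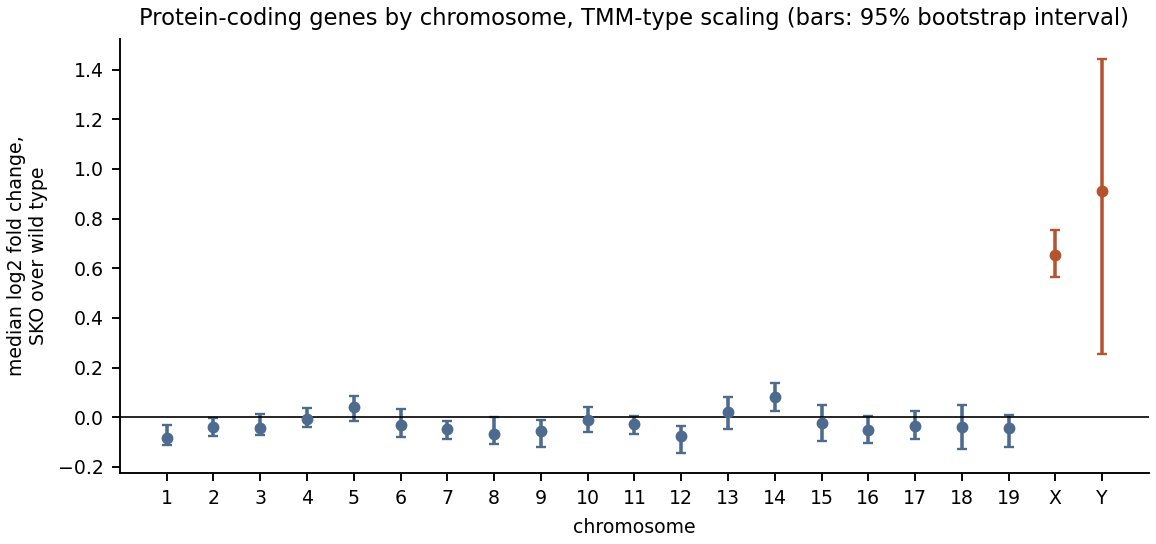
Median log2 fold change, SKO over wild type, of protein-coding genes on each chromosome under TMM-type scaling, with 95% bootstrap intervals over genes as bars. The X median is 0.65 and the Y median 0.91, and the autosomes lie between -0.08 and 0.08.

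Markers of somatic testis cells, which lie outside the germ line, also moved with the genotype. The Sertoli cell list had 11 tested members with a median 0.81 above all genes (camera, adjusted p = 0.000941, or 0.519 as an adjusted p with an estimated correlation). The Leydig cell list had 11 tested members with a median 0.67 above all genes (camera, adjusted p = 0.00130, or 0.402 as an adjusted p with an estimated correlation). With 1 library left out the Sertoli median ran from 0.48 to 1.04 and the Leydig median from 0.59 to 1.10, and the Leydig list did not pass without SKO replicate 1 (adjusted p = 0.0542). No member of either list passed the test over all genes with the deposited values, and under TMM-type scaling Clu rose (scaled log2 fold change 2.03, limma adjusted p = 0.0410, against 0.0853 for the deposited values). Adjusted over the list alone, 2 Sertoli markers rose, namely Clu, the clusterin gene, at 5.57 ± 2.14 against 27.7 ± 3.69 FPKM and Ctsl, the cathepsin L gene, at 7.44 ± 2.99 against 28.0 ± 7.71 FPKM (wild type against SKO, SD, n = 3). Adjusted over the list alone, 5 Leydig markers rose: the peptide hormone gene Insl3, the steroid synthesis genes Cyp11a1, Cyp17a1 and Hsd3b1, and Fabp3. Insl3 went from 5.43 ± 4.13 to 36.8 ± 17.4 FPKM and Cyp17a1 from 2.58 ± 1.71 to 18.0 ± 7.16 FPKM. The Leydig marker Star, at 1.59 ± 0.434 and 3.81 ± 2.20 FPKM, did not pass. The combined list of peritubular, endothelial, macrophage and blood markers, with 14 tested members, did not pass as a list (median 0.15 above all genes, camera, adjusted p = 0.646), and its members differed in direction. Dcn, the decorin gene of connective tissue, rose from 1.11 ± 0.289 to 8.96 ± 1.33 FPKM (log2 fold change 2.24, limma adjusted p = 0.0470). Adjusted over the list alone, 4 members rose (Dcn and the smooth muscle genes Acta2, Cnn1 and Myh11) and 4 fell, the globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt. Hbb-bs went from 27.5 ± 9.53 to 9.38 ± 5.81 FPKM. Under TMM-type scaling Dcn and Acta2 rose over all genes, with a limma adjusted p of 0.0775 for Acta2 with the deposited values.

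Among chromatin genes, the list of testis histone variants and histone exchange lay above all genes but did not pass the test. Its 30 tested members had a median 0.27 above all genes (camera, adjusted p = 0.0505). It passed in 12 of 22 other settings, under TMM-type scaling among them (adjusted p = 0.0326, or 0.399 as an adjusted p with an estimated correlation). Adjusted over the list alone, 3 members rose with the deposited values and 27 did not pass, and 5 rose under TMM-type scaling. The 3 were H2bc1, its H2A partner H2ac1, at 3.98 ± 1.94 against 17.4 ± 7.73 FPKM, and H2al1m. The replacement histone H3.3 gene H3f3b had 42.0 ± 16.3 FPKM in wild type and 131 ± 51.5 FPKM in SKO and H3f3a had 63.4 ± 30.2 and 106 ± 31.4 FPKM. The heterochromatin and chromocenter list, which bears on the process named in the series title, had 36 tested members, none of which passed, and a median 0.23 below all genes (-0.23, camera, adjusted p = 0.646). Its members with the highest density were Trim28, a corepressor of heterochromatin, at 75.9 ± 14.2 and 96.8 ± 20.7 FPKM, and the histone chaperone gene Daxx, at 26.4 ± 9.48 and 36.9 ± 14.5 FPKM. The 5 tested protamine and transition protein genes had a median of -0.46 relative to all genes (camera, adjusted p = 0.646). Tnp1 had 44.0 ± 11.8 and 31.7 ± 7.05 FPKM, and Prm3 had 31.2 ± 13.5 and 61.2 ± 23.8 FPKM. The round spermatid transcription regulators, 31 tested members, had a median of 0.0002 relative to all genes and a mean of -0.05 (camera, adjusted p = 0.809). Crem, a master regulator of post-meiotic transcription, had 226 ± 83.9 FPKM in wild type and 221 ± 88.5 FPKM in SKO. Kctd19 of the same list fell under TMM-type scaling (127 ± 51.3 to 41.2 ± 13.1 FPKM, scaled log2 fold change -1.74, limma adjusted p = 0.0410), and with the deposited values had an adjusted p of 0.275.

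Genes of the translation machinery gave no list past the test with the deposited values. The cytosolic ribosomal proteins, 81 tested members, had a median 0.31 above all genes (camera, adjusted p = 0.0588). It passed in 7 of 22 other settings, under TMM-type scaling among them (adjusted p = 0.0383, or 0.845 as an adjusted p with an estimated correlation). Its densest members were the testis paralogue Rpl39l, at 172 ± 49.6 and 330 ± 103 FPKM, and Rpl38, at 165 ± 56.0 and 203 ± 87.0 FPKM, and none of the 81 passed the test over all genes. Under TMM-type scaling 4 rose when adjusted over the list alone. The translation initiation, elongation and release factors, 58 tested members, had a median of -0.07 relative to all genes (camera, adjusted p = 0.646), with Eef1a1 at 194 ± 59.7 and 307 ± 121 FPKM and Eif3c at 118 ± 37.8 and 162 ± 57.5 FPKM. The polyamine and hypusine list, 14 tested members, contains Eif5a, the one member that fell, and 13 did not pass. Its median was 0.20 above all genes and its mean -0.02 (camera, adjusted p = 0.646). Under TMM-type scaling Eif5a fell, 1 member rose and 12 did not pass when adjusted over the list alone. EIF5A is known to help ribosomes across runs of prolines, and the fixed list of polyproline-rich proteins, 55 tested members, had a median of -0.08 relative to all genes (camera, adjusted p = 0.494) with 0 members past the limma test over all genes or adjusted over the list alone. Wbp11 of that list had 86.4 ± 25.3 and 186 ± 46.7 FPKM and Sf1 had 84.5 ± 27.5 and 92.8 ± 20.1 FPKM. The cytosolic chaperones had a median of 0.001 and a mean of -0.008 relative to all genes (43 tested members, camera, adjusted p = 0.936), with Tcp1 at 1512 ± 422 and 1588 ± 590 FPKM, and under TMM-type scaling 3 rose and 1 fell when adjusted over the list alone. The proteasome list had a median of -0.0008 (38 tested members, camera, adjusted p = 0.646, past the threshold in 1 of 22 other settings), with Psmb6 at 100 ± 34.1 and 113 ± 42.7 FPKM. Genes of the integrated stress and unfolded protein responses had a median 0.16 above all genes (32 tested members, camera, adjusted p = 0.185), with Hspa5 at 350 ± 96.6 and 569 ± 215 FPKM and Hsp90b1 at 722 ± 218 and 530 ± 213 FPKM.

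**Figure D3:**
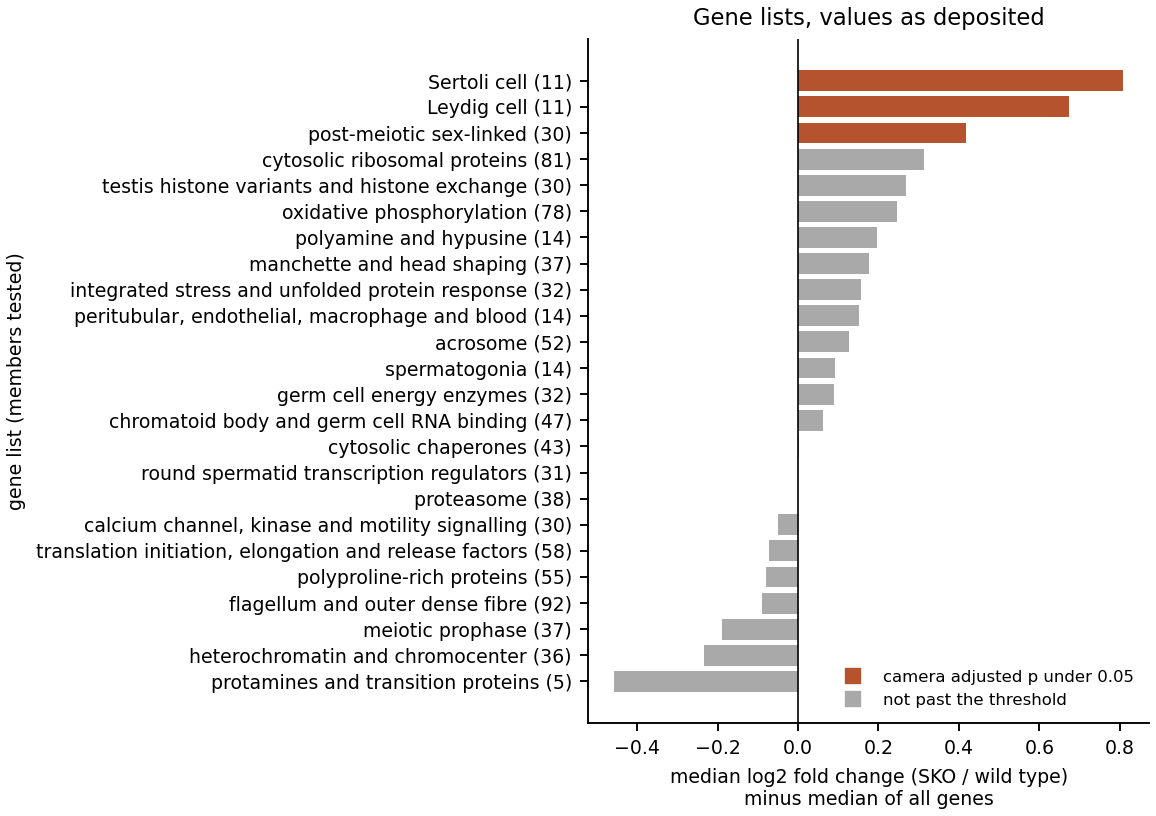
Median log2 fold change, SKO over wild type, of each of the 24 tested gene lists minus the median of all tested genes, with the deposited values and the number of tested members in parentheses. Orange bars mark the 3 lists with a camera adjusted p under 0.05, at 0.81 for Sertoli cell, 0.67 for Leydig cell and 0.42 for post-meiotic sex-linked genes.

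The lists of structures that spermatids build and of their energy supply did not pass the test with the deposited values. In other settings the oxidative phosphorylation list passed in 5 of 22 (smallest camera adjusted p = 0.000305, without SKO replicate 1), the acrosome list in 3 of 22 (0.0340, without SKO replicate 1) and the flagellum list in 2 of 22 (0.00121, lower in SKO, with quantile normalization). The acrosome list had 52 tested members and a median 0.13 above all genes (camera, adjusted p = 0.149), with Spink2 at 830 ± 320 FPKM in wild type and 1015 ± 390 FPKM in SKO and Acrbp at 548 ± 197 and 686 ± 291 FPKM. The flagellum and outer dense fibre list had 92 tested members and a median of -0.09 relative to all genes (camera, adjusted p = 0.373), with Meig1 at 950 ± 351 and 1800 ± 733 FPKM. Under TMM-type scaling the acrosome gene Spaca9 rose from 16.2 ± 3.10 to 53.0 ± 10.9 FPKM (limma adjusted p = 0.0455) and the central-pair gene Spef2 fell from 32.7 ± 11.9 to 13.5 ± 3.56 FPKM (limma adjusted p = 0.0468), with adjusted p of 0.165 and 0.320 for the deposited values and 4 of 20 alternative settings passed by each. Under that scaling 10 acrosome members rose and 1 fell, and 1 flagellum member rose and 7 fell, adjusted over the list alone, against 0 in either list with the deposited values. The manchette and head shaping list had a median 0.18 above all genes (37 tested members, camera, adjusted p = 0.494), with Psmc3 at 1126 ± 401 and 1213 ± 369 FPKM. Calcium channel, kinase and motility signalling genes had a median of -0.05 (30 tested members, camera, adjusted p = 0.646), with Catsperz at 415 ± 179 and 579 ± 218 FPKM. The germ cell energy enzymes had a median 0.09 above all genes (32 tested members, camera, adjusted p = 0.646), with the sperm lactate dehydrogenase gene Ldhc at 3846 ± 1268 and 3711 ± 1355 FPKM. The oxidative phosphorylation list had a median 0.25 above all genes (78 tested members, camera, adjusted p = 0.123), with Ndufc1 at 442 ± 72.6 and 744 ± 275 FPKM.

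Lists of germ cell RNA binding and of other germ cell stages did not pass with the deposited values either. The chromatoid body and germ cell RNA binding list had a median 0.06 above all genes (47 tested members, camera, adjusted p = 0.646). Adjusted over the list alone, 1 member rose, the germ cell RNA-binding gene Dazl, and 1 fell, Samd4b. Under TMM-type scaling 5 rose and 4 fell when adjusted over the list alone. Under TMM-type scaling Ybx2, which stores translationally repressed mRNAs in germ cells, rose from 102 ± 38.2 to 299 ± 89.6 FPKM (limma adjusted p = 0.0473), with an adjusted p of 0.275 for the deposited values, and it passed in 4 of 20 alternative settings. The meiotic prophase list had a median of -0.19 relative to all genes (37 tested members, camera, adjusted p = 0.558, past the threshold in 1 of 22 other settings), with Hspa2 at 223 ± 82.2 and 174 ± 68.0 FPKM and Syce3 at 49.5 ± 13.6 and 103 ± 52.8 FPKM. The spermatogonia list had a median 0.09 above all genes (14 tested members, camera, adjusted p = 0.292), with Ddx4 at 155 ± 47.5 and 136 ± 52.2 FPKM and Pcna at 37.1 ± 8.74 and 46.6 ± 15.5 FPKM. Adjusted over the list alone, 1 spermatogonia member rose, again Dazl, and 13 did not pass.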

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

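The settings marked as added, and those of the X-linked comparison, were chosen after the data were seen. The fall of Eif5a kept its direction and its side of the threshold under all 20 alternatives (log2 fold change -4.35 to -2.85, adjusted p up to 0.0369), with -4.12 to -3.70 when 1 library was left out. The number of genes past the threshold, 20 with the deposited values, was the less stable result, and the cause was not tested. It was 4 with a pseudocount of 5, 5 with no filter on low values, 86 at a mean of at least 5 FPKM, 159 with TMM-type scaling, 446 with quantile normalization (248 higher, 198 lower), 63 with robust eBayes, 5 with a replicate block and 64 at an adjusted p under 0.1. Added settings gave 844 (TMM-type scaling at a mean of at least 5 FPKM, 501 higher and 343 lower), 4 (TMM-type scaling and replicate block), 217 (protein-coding rows with TMM-type scaling) and 9 (identical rows counted once). Leaving out 1 library, which leaves fewer samples, gave 4 to 31 genes, and 4 to 28 in place of the 159 under TMM-type scaling. At least 157 of the 159 kept their sign, but they were chosen on all libraries, so this gives no further support. The 3 lists past the threshold became 6 with no filter, 5 with TMM-type scaling, 6 with quantile normalization (4 higher, 2 lower), 6 with a replicate block, 0 with an estimated correlation, and 5 and 7 in the added TMM-type settings with a replicate block and with protein-coding rows alone. Leaving out 1 library gave 3 to 7 lists under either scaling. The sex-linked list (0.418) passed in 20 of 22 alternatives, not with an estimated correlation (0.418, adjusted p = 0.780) or by fry (0.418, adjusted p = 0.0886), with 0.453 to 0.679 when 1 library was left out. Under TMM-type scaling fry gave an adjusted p of 0.00958 for this list, 0.0423 for the Sertoli list and 0.0819 for the Leydig list. There 0 lists passed with an estimated correlation. The Sertoli list (0.809) passed in 21 of 22, not with an estimated correlation (0.809, adjusted p = 0.519), with 0.483 to 1.04. The Leydig list (0.675) passed in 19 of 22, not with an estimated correlation (0.675, adjusted p = 0.402), with added TMM-type scaling at a mean of at least 5 FPKM (1.51, adjusted p = 0.0525) or without SKO replicate 1 (adjusted p = 0.0542), with 0.587 to 1.10. The X-linked minus autosomal median (0.683) moved to 0.362 with a pseudocount of 5 and 0.392 with no filter, with 0.645 to 0.753 when 1 library was left out. The 50 X-linked genes past the threshold became 4 with the deposited values, all H2al1 genes with the same 6 values. Under TMM-type scaling they became 0 to 9 when 1 library was left out. Among 67 named genes 1128 values kept their side of the threshold, 126 became stronger and 79 weaker. Of these values 48, in 11 genes, had the other sign, 0 of them past the threshold in either setting. Same-numbered samples correlated in their deviations at 0.0926, 0.000158 and 0.0243, and not every sample correlated best with its own number. With 3 samples per group this check cannot exclude that same-numbered samples belong together. Count-based normalization and the test of proline runs were not run, for want of counts and coding sequences. Depth limits low genes most, since 1 read is worth 0.122 to 0.243 FPKM.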

Other observations

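The test of shared reads without clone names and the Slx family was chosen after the results were seen. So were the tests of somatic cells and of genomic span and level as sources of the X-linked rise. The test on the globin genes and the test of expression level against genomic span were also chosen after the results were seen. The other tests below were chosen before the result that they measure was seen.

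Of the X-linked genes counted above, 3 more that rose under TMM-type scaling are named here, chosen after their values were seen. The homeobox genes Tgif2lx1 and Tgif2lx2, which share the same 6 values, went from 29.9 ± 8.11 to 87.4 ± 29.4 FPKM (SD, n = 3 per group, limma adjusted p = 0.0410). Fmr1nb, a testis gene next to Fmr1, went from 13.0 ± 3.50 to 58.0 ± 25.0 FPKM (limma adjusted p = 0.0410).

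X-linked genes were higher in the SKO samples. Reads shared between copies are argued against as the whole cause of the median shift. The 55 X-linked genes with no relative of the same name root had a median shift of 0.495 against autosomal genes (95% bootstrap interval 0.341 to 0.594). With clone names and the Slx family left out, 34 of them had 0.502 (0.341 to 0.594), although names stand in for sequence here. The root is the leading letters of a symbol, so Ssxa1 is among the 34 although Ssxb genes were tested too. Of the 50 X-linked genes that rose under TMM-type scaling, only 3 are in the 55. All 3 are left out of the 34, so shared reads stay open for those calls. Bias by genomic span and mean level is also argued against. X-linked genes exceeded the 10 autosomal genes nearest in level and span by a median of 0.622 (0.511 to 0.703). The level was the mean over all 6 libraries, SKO included, and the interval measures the spread between genes and not between samples. Transcript and coding length were not used, so a bias by those lengths was not tested. Somatic cells in the SKO samples would not raise genes used by germ cells alone. Yet 19 such sex-linked genes had a median shift of 0.925 (0.374 to 1.62). This set was chosen after the results were seen and was not kept apart from the fixed sex-linked list. It does not cover germ cells of other stages as a source. For the 343 X-linked genes outside this set and that list, the median shift was 0.676 (0.594 to 0.774). For them somatic cells and spermatids cannot be told apart, because their level in somatic cells is not given here. Further candidate explanations that stay open and untested are a genotype effect on the sex chromosomes of spermatids and a different mix of spermatid steps in the samples. RNA levels would be needed to tell a change of mRNA from a change on the ribosomes. They would not by themselves separate these explanations.

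Part of the markers of Leydig, Sertoli and peritubular cells were higher in the SKO samples, which are labelled round spermatids, but the Sertoli and Leydig lists did not pass with an estimated correlation (adjusted p = 0.519 and 0.402) and the combined list with peritubular markers did not pass (adjusted p = 0.646). A lower share of spermatids that raised every other cell type alike would raise the 4 globin genes of blood cells too. They fell instead, by a mean of 1.52 relative to all genes (value -1.52, 95% interval over the 4 genes -1.71 to -1.33). That interval measures the spread between genes, which can share reads, and not between samples. The fall was seen before the test was chosen, so the test is not independent of it. More Leydig, Sertoli and peritubular cells may be present in the SKO samples, but a second set of markers did not decide it. Its 23 tested genes of 40 listed had a median shift of 0.499, and 19 of the 23 lay above the all-gene median. The interval of 0.168 to 0.852 was wholly positive, but its lower bound missed the limit set beforehand. The set includes Bgn and Flna, which are X-linked. In SKO, Insl3 stood at 36.8 FPKM and Clu at 27.7 FPKM, against 3711 FPKM for the germ cell gene Ldhc. Expression of these genes by the SKO spermatids themselves was not tested.

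Autosomal genes with a long genomic span had lower fold changes than those with a short span (Spearman correlation over 10771 genes -0.177, genes not being independent). The median log2 fold change was 0.12 in the tenth with the shortest spans and -0.11 in the tenth with the longest. Expression level differing with span is argued against as the whole cause, since the correlation was negative in each of 5 bins of mean level. It grew stronger with level, at -0.0689, -0.122, -0.144, -0.226 and -0.288 from the lowest bin to the highest. A length bias that varies between libraries regardless of genotype remains possible, because the slopes of the groups overlapped and their exact permutation test gave p = 0.2. Coding length is not used here, so whether the trend follows the length that ribosomes travel stays open.

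The genotype grouping is 1 of only 10 ways to split 6 libraries into 3 and 3, so no share under 0.05 can be reached. The real grouping gave 20 genes past the threshold and the highest other split 7 (1 of 10 splits as large). With TMM-type scaling it gave 159 and the highest other split 7 (1 of 10 as large). For gene lists the real grouping gave 3 and the highest other split 11 (4 of 10 as large), and with TMM-type scaling 5 against 10 (3 of 10 as large). For the X-linked minus autosomal median it gave 0.683 and the highest other split 0.340 (1 of 10 as large). The splits with the most lists join WT replicates 1 and 2 with SKO replicate 1, or WT replicate 1 with SKO replicates 1 and 3, and called 6 and 3 genes with the deposited values.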
